A study of Homo sapiens with 14 samples.

How the data were processed

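The series measured gene expression and ribosome occupancy in K562-dCas9 cells, a human chronic myelogenous leukaemia line that carries a catalytically dead Cas9 fused to BFP and the KRAB repressor domain, so that a guide RNA silences the promoter it binds (CRISPR interference). The cells also carried a GFP reporter mRNA that lacks a stop codon. Per the labels, guides were delivered by lentivirus, cells holding a guide were sorted by their red fluorescent marker, and cells were treated with cycloheximide before freezing. The groups were a non-targeting guide (sgGal4), guides against GIGYF2, EIF4E2, ZNF598 and NEMF, and cells without a guide or reporter (called cells without a guide below, labelled none). Each of the 6 groups had 2 replicates, giving 12 total RNA libraries. The footprints came as 2 pooled samples, each split by the submitters into 6 tables, giving 12 footprint libraries. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

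GEO labels both footprint pools as mixed. The guide of each footprint table was therefore taken from the name the submitters gave the table and its header, and the replicate from the label of the pool. The targeted genes were then checked in every table.

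The deposited values are whole-number read counts per gene and region (5′ UTR, coding region, 3′ UTR and exons). Per the file headers they were made with the count command of plastid on gene models of GRCh38 release 92 with the engineered transcripts added. Per the file headers, total RNA reads of 24 to 51 nt were counted at their 5′ end, and footprints of 26 to 30 nt at a P-site offset. Per the submitters' processing notes, Bowtie 1.2 and TopHat2 2.1.1 were used with GRCh38. How a read that maps to several genes was counted is not given in the sources used here, so genes with near-identical copies (histones, globins, ribosomal proteins and their pseudogenes) are uncertain. The RPKM columns beside the counts were not used. Each table has 56844 entries, or 56843 in cells without a guide, where the reporter is absent. Of these, 936 merge several genes. They stayed in the library totals, tests and counts of changed genes (22 of the 418 in sgGIGYF2 total RNA), but were left out of lists and naming. Of 55906 entries with a single Ensembl gene, 55340 have a symbol in the gene name table. The reporter and dCas9 transcripts were counted apart from genes, and were left out of comparisons with cells without a guide, where the dCas9 entry has another counted length.

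Reads in coding regions were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling within each assay, filterByExpr by group, and the quasi-likelihood test (glmQLFit, glmQLFTest) with all 12 libraries of an assay sharing 1 estimate of the spread. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called changed when its adjusted p was under 0.05. Translational efficiency (TE), the footprint change minus the total RNA change on the log2 scale, was tested as an interaction in 1 edgeR model over all 24 libraries. The tests covered 9929 genes for total RNA, 9582 for footprints and 9371 for TE. All fold changes are log2 values against sgGal4 unless another control is named. CPM are counts over the TMM-scaled library size in units of 1e6, given as mean ± SD over 2 libraries. Positions of targeted genes and their neighbours come from the RefSeq table of GRCh38. That table gives no strand, so a neighbour is a gene whose span lies within 10 kb of either end of the target, in place of its transcription start.

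The 19 gene lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation, adjusted over 95 tests per readout (19 lists in 5 comparisons). Of those, 24 tests passed for total RNA, 35 for footprints and 19 for TE with the preset correlation, and 0, 8 and 0 with the estimated one. A list's median, mean and test differed in sign in 18, 10 and 20 of the 95 tests, but in 0 of those that passed. Named genes are the 4 targets, GIGYF1 and EIF4E; per knockdown, the 8 largest changes in each direction for total RNA and TE among genes past the threshold with a mean of at least 10 CPM and both knockdown libraries beyond both sgGal4 libraries; the 4 largest for the other comparisons; and up to 4 members per list past the threshold with the smallest adjusted p. Genes of a count of 5 or fewer may also be named. The reporter, the dCas9 transcript and the further genes of the direct footprint comparison were chosen after their values were seen.

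Counts simulated from these libraries' means and sizes, with 200 genes changed, tested the edgeR step. For sgGIGYF2 total RNA (9829 genes run), 71.7% of genes changed by 1 on the log2 scale and 96% of those changed by 2 were recovered, with 14 false calls among 181. For its footprints (9448 genes) these were 70.7% and 97%, with 9 false among 176. For its TE (9219 genes) they were 46% and 87.8%, with 6 among 138. False calls may be more frequent against sgGal4, whose replicates lay furthest apart. Of lists of 30 genes, simulated on sgNEMF footprints, the preset correlation called 20 of 20 shifted and 1 of 380 unchanged ones. An estimated one called 20 and 0. Genes were drawn independently, so lists whose genes vary together were not tested.

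Total RNA libraries held 1037389 (sgGal4 replicate 1) to 6045842 coding-region counts, and footprint libraries 1010547 (sgZNF598 replicate 1) to 5366480. Replicates of a group were not duplicates of each other: their counts differed by more than sampling noise in every pair (chi-square per degree of freedom 2.28 to 7.96). The replicates furthest apart were those of sgGal4, with an SD of 0.366 (total RNA) and 0.34 (footprints) for the log2 difference between them, and sgGal4 is the control of every comparison.

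Footprint libraries of the same number share a pool per the labels, so footprint and TE fits were also made with the replicate number as a block. Deviations from the group means correlated by more than 0.1 in 4 of 15 pairs of groups (median 0.0359). The blocked value stands beside a footprint or TE result where it changes a call or moves a count by more than 1.5 times. The other alternatives were DESeq2 size factors, no filter, a filter of at least 10 CPM in 2 libraries, DESeq2 1.42.0, limma on the log2 ratio (TE), only the 2 groups compared, sgGal4 and cells without a guide as a joint control, each library left out in turn, and, added after the data were examined, exon reads for total RNA and effect correlations without sgGal4 replicate 1. Comparisons that share the sgGal4 libraries were set beside 100 simulations of unchanged groups with the same controls. The simulated overlap of calls was added after the data were examined. It was run for unchanged groups and for groups that each got the log2 changes of their called genes at randomly drawn genes of similar level. Positional data along transcripts, splicing and intron reads were not analysed here.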

Results

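GIGYF2 and 4EHP (the product of EIF4E2, a cap-binding protein that does not recruit the initiation machinery) act together to repress translation of mRNAs, and the study asked how this complex acts on defective mRNAs on which ribosomes stall. ZNF598 senses collided ribosomes and NEMF extends and marks the nascent chain on the released large subunit. Total RNA and ribosome footprints were measured with a guide against each of these genes (sgGIGYF2, sgEIF4E2, sgZNF598, sgNEMF), with sgGal4 and in cells without a guide. Each group had 2 replicates per assay (n = 2 for every mean ± SD). Total RNA libraries held a median of 3413907 coding-region counts. The sgGal4 libraries held 1037389 and 3210038 counts of total RNA and 1838585 and 2534480 of footprints. In total RNA, mitochondrial rRNA took 22.7% to 34.7% of exon reads, and sgGal4 replicate 1 had both the fewest counts and the highest rRNA share. It also lay furthest from the other libraries on the second principal component of total RNA, at 30.31 against 11.36 for sgGal4 replicate 2, and on that of footprints, at 20.16 against 8.46.

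Each guide silenced its target in both assays. GIGYF2 (ENSG00000204120; GRCh38 chromosome 2, 232697331 to 232860605) fell by 2.90 on the log2 scale in sgGIGYF2 total RNA (SE 0.197, adjusted p = 1.36e-07), from 78.7 ± 9.79 CPM in sgGal4 to 10.7 ± 0.26 CPM. It fell by 3.80 in footprints (SE 0.261, adjusted p = 3.96e-14). EIF4E2 (ENSG00000135930; chromosome 2, 232550689 to 232583644) fell by 3.94 in sgEIF4E2 total RNA (SE 0.185, adjusted p = 2.47e-10) and by 3.95 in footprints (SE 0.253, adjusted p = 3.13e-15), leaving 6.52% and 6.46%. ZNF598 (ENSG00000167962; chromosome 16, 1997654 to 2009821) fell by 2.25 in sgZNF598 total RNA (SE 0.207, adjusted p = 1.9e-05) and by 2.45 in footprints (SE 0.388, adjusted p = 2.83e-05), leaving 21% and 18.3%. NEMF (ENSG00000165525; chromosome 14, 49782083 to 49852788) fell by 4.01 in sgNEMF total RNA (SE 0.212, adjusted p = 2.02e-09) and by 3.48 in footprints (SE 0.271, adjusted p = 9.51e-13), leaving 6.19% and 8.94%. All 8 calls held in every alternative run, with each library left out in turn included (highest adjusted p 0.00408, for ZNF598 footprints).

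**Figure D1:**
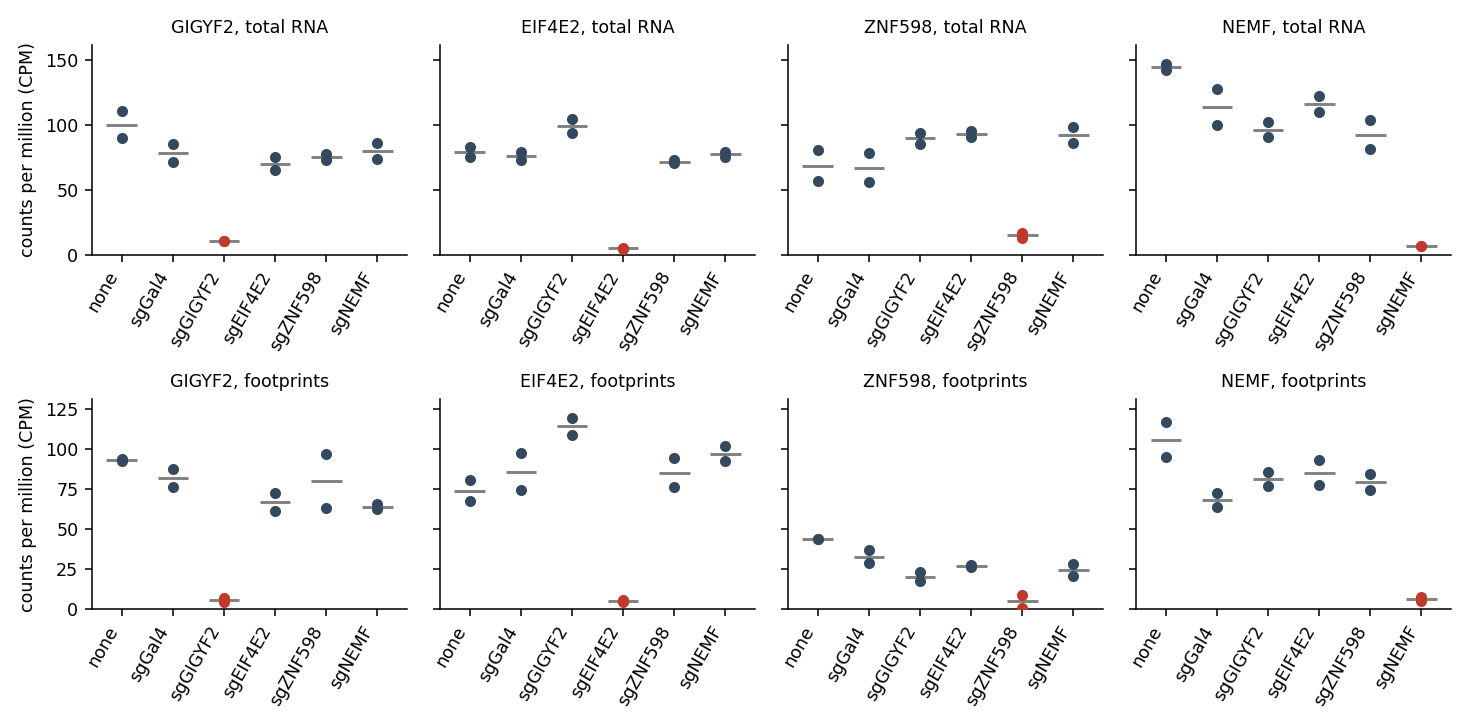
Level of the 4 targeted genes in each total RNA library (top) and footprint library (bottom), in CPM on a linear axis. Points are single libraries, bars are the mean of 2, and red marks the guide against that gene, which has the lowest level in every panel.

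Total RNA of the targets did not pass the test under the other guides. EIF4E2 in sgGIGYF2 was at 0.37 (SE 0.131, adjusted p = 0.105), GIGYF2 in sgEIF4E2 at -0.19 (SE 0.149, adjusted p = 0.462). In cells without a guide NEMF footprints were higher by 0.61 (SE 0.163, adjusted p = 0.00451), and the TE of ZNF598 was lower in sgGIGYF2, at -1.0 (SE 0.325, adjusted p = 0.0453). GIGYF1, the paralog of GIGYF2, passed the test in no comparison, with a total RNA value of 0.13 in sgGIGYF2 (SE 0.160, adjusted p = 0.68). EIF4E, the cap-binding subunit of the initiation complex and paralog of EIF4E2, rose by 0.97 in sgGIGYF2 footprints (SE 0.160, adjusted p = 3.12e-05) and by 1.03 in TE (SE 0.211, adjusted p = 0.00424), with total RNA at -0.05 (SE 0.148, adjusted p = 0.874). Its TE also rose in sgZNF598, by 0.96 (SE 0.225, adjusted p = 0.00503), where its total RNA fell by 0.59 (SE 0.148, adjusted p = 0.0141).

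TIGD1, whose annotated span ends 131 bp from that of EIF4E2 (chromosome 2, 232543883 to 232550557), fell by 3.97 in sgEIF4E2 total RNA (SE 0.488, adjusted p = 0.000267), leaving 6.38%. It had too few footprints to be tested. Near ZNF598, total RNA of SYNGR3 rose by 2.30 in sgZNF598 (SE 0.521, adjusted p = 0.00869), with lower TE (-2.76, SE 0.664, adjusted p = 0.00619), and footprints of NPW fell by 1.64 (SE 0.403, adjusted p = 0.00524). SYNGR3 total RNA was also higher in cells without a guide (2.23, SE 0.538, adjusted p = 0.00666), so its rise is not specific to sgZNF598. GFER, also near ZNF598, in sgZNF598, and KLHDC2, whose span overlaps NEMF, in sgNEMF did not pass in any readout.

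Footprints on the non-stop reporter were higher after GIGYF2 knockdown. The reporter rose by 0.61 in sgGIGYF2 footprints (SE 0.137, adjusted p = 0.00149), from 184 ± 22.5 to 281 ± 5.54 CPM. This call held in all 10 alternatives (log2 changes 0.49 to 0.75, adjusted p 0.000122 to 0.0207). Its total RNA was at 1738 ± 27.7 CPM against 1487 ± 115 in sgGal4, a log2 value of 0.23 that did not pass (SE 0.114, adjusted p = 0.247), nor did its TE of 0.40 (SE 0.189, adjusted p = 0.17). In sgEIF4E2 the reporter stood at -0.20 in total RNA, 0.11 in footprints and 0.33 in TE (adjusted p = 0.297, 0.683 and 0.308). Tested directly, its footprints did not pass between sgGIGYF2 and sgEIF4E2 (0.50, SE 0.136, adjusted p = 0.141). They were higher in sgGIGYF2 than in sgZNF598 (0.84, SE 0.146, adjusted p = 9.24e-05) and sgNEMF (1.02, SE 0.142, adjusted p = 4.13e-06). Its total RNA was also higher than in sgNEMF (0.63, SE 0.114, adjusted p = 0.00509) and did not pass against sgZNF598 (0.30, adjusted p = 0.0932), and its TE passed against neither (0.39 and 0.53, adjusted p = 0.465 and 0.379). In sgNEMF the reporter was at -0.40 in total RNA and -0.40 in footprints (adjusted p = 0.053 and 0.0851). The total RNA value passed in 6 of 11 alternatives and the footprint value in 1 of 10.

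**Figure D2:**
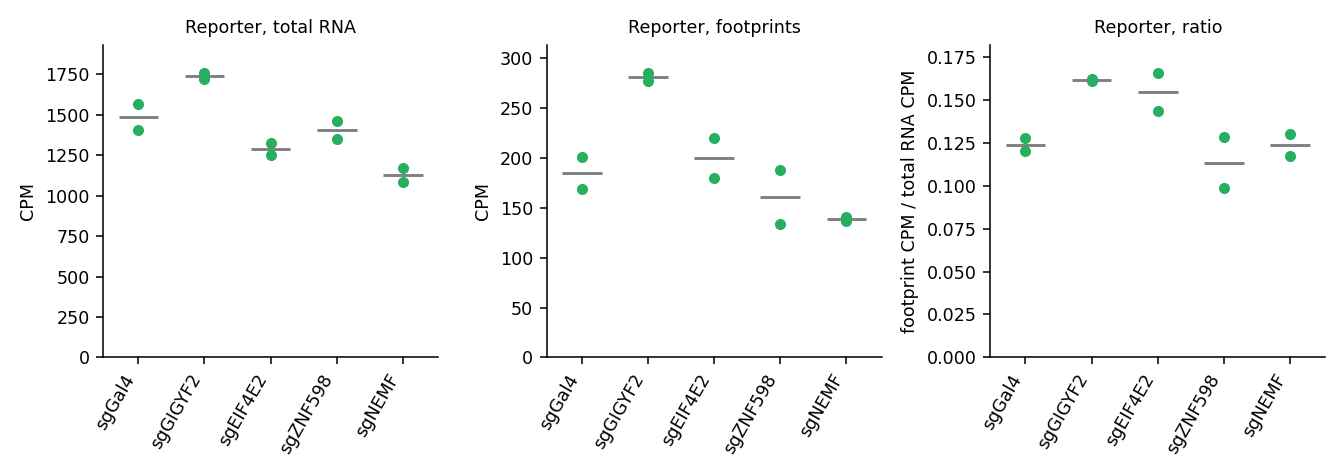
Non-stop reporter in each library of the 5 groups that carry it: total RNA CPM, footprint CPM, and footprint CPM over total RNA CPM of the same group and replicate number (linear axes from 0). Points are single libraries and bars the mean of 2, and both sgGIGYF2 footprint libraries lie above both sgGal4 libraries.

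In total RNA, targets of ATF4, the transcription factor of the integrated stress response, were lower in sgGIGYF2 than in sgGal4, but not lower than in cells without a guide. Of 37 measured ATF4 targets 9 fell and 0 rose (14 and 1 adjusted over the list alone, camera adjusted p = 0.00179, adjusted p = 0.415 with an estimated correlation). The list median against cells without a guide was 0.53, with 19 targets higher and 0 lower. ATF5 fell by 1.41 (SE 0.18, adjusted p = 0.000726), MTHFD2, a mitochondrial folate enzyme, by 1.11 (SE 0.16, adjusted p = 0.00153) and DDIT3 (CHOP) by 0.96 (SE 0.13, adjusted p = 0.00113). The ER chaperone HSPA5 rose by 1.27 and its cochaperone SDF2L1 by 1.01 (adjusted p = 0.0422 and 0.0157). Of the unfolded protein response, 4 of 23 genes rose and 0 fell (7 and 0 adjusted over the list alone, adjusted p = 0.00445, adjusted p = 0.415 with an estimated correlation, median 0.01 against cells without a guide with 2 higher and 1 lower). Replication-dependent histone mRNAs were lower in 11 of 36 (22 adjusted over the list alone, adjusted p = 4.41e-07, adjusted p = 0.58 with an estimated correlation, median -0.20 against cells without a guide with 1 higher and 5 lower). Among them were H4C9 (-0.72) and H2AC11 (-0.65). Proteasome subunits rose in 4 of 34 and fell in 0 (5 and 0 adjusted over the list alone, adjusted p = 0.022, adjusted p = 0.415 with an estimated correlation), but against cells without a guide their median was -0.05 (1 higher, 3 lower). The megakaryocyte integrin ITGA2B (1.13) and THBS1 (1.42) rose, 2 of 8 in that list (3 adjusted over the list alone, adjusted p = 0.00718, adjusted p = 0.317 with an estimated correlation, median 0.74 against cells without a guide with 2 higher and 0 lower). Largest changes are given here and below only among genes with a mean of at least 10 CPM (in both assays for TE) and both libraries of the group beyond both sgGal4 libraries. The small heat shock protein HSPB1 (2.04, SE 0.42), CCDC86 (1.47), TUBA4A and CHERP (1.36 each), SDR39U1, RANBP1, DNAJC30 and SPTSSA had the largest increases within these limits. HSPB1 had 0 counts in sgGal4 replicate 1 and 10.34 CPM in replicate 2, so its fold change depends on that library. After GIGYF2 itself, the VEGF receptor FLT1 (-1.82, SE 0.27), GRAP2 (-1.70), coagulation factor F8 (-1.44), ATF5, ZNF490, IFT81 and H2BC21 (-1.27) had the largest decreases within them. HSPB1, CCDC86, CHERP and RANBP1 (2.07) also passed as higher, and GRAP2, F8, ATF5, ZNF490 and H2BC21 as lower, in cells without a guide, and RANBP1 turned to -0.15 with the joint control.

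The edgeR test called 418 genes in sgGIGYF2 total RNA, 194 higher and 224 lower. Without sgGal4 replicate 1 the count was 24, without sgGal4 replicate 2 it was 678, without sgGIGYF2 replicate 1 it was 13 and without sgGIGYF2 replicate 2 it was 45. Of 34 named values past the threshold, 25, 14, 28 and 24 then lost their call and 0 changed sign, and with sgGal4 and cells without a guide as a joint control 15 genes passed. Members of the lists that passed without sgGal4 replicate 1 were: ATF4 targets 4 lower (median -0.25), unfolded protein response 0 (median 0.20), AU-rich mRNAs 0 (median 0.14), megakaryocyte genes 0 (median 0.48), histones 1 lower (median -0.41) and proteasome 0 (median 0.15).

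In footprints ATF4 targets were also lower in sgGIGYF2 than in sgGal4, and also not lower than in cells without a guide. Altogether 21 of 37 ATF4 targets fell and 0 rose (24 and 1 adjusted over the list alone, median -0.43, adjusted p = 5.18e-08, adjusted p = 0.0375 with an estimated correlation). The median against cells without a guide was 0.44, with 20 higher and 1 lower. TRIB3, a pseudokinase induced by ATF4, fell by 1.2 in sgGIGYF2 (SE 0.12, adjusted p = 4.79e-09), DDIT3 by 1.29 (SE 0.20, adjusted p = 1.23e-05), the tRNA synthetase WARS1 by 0.65 and the amino acid transporter subunit SLC3A2 by 0.67. Proteasome subunits rose in 16 of 34 and fell in 0 (18 and 0 adjusted over the list alone, median 0.28, adjusted p = 1.11e-05, adjusted p = 0.0375 with an estimated correlation, median 0.09 against cells without a guide with 5 higher and 5 lower). PSMB2 was at 0.78 and the assembly factor POMP at 0.79. Cytosolic ribosomal proteins rose in 37 of 67 and fell in 5 (44 and 7 adjusted over the list alone, adjusted p = 3.42e-08, adjusted p = 0.288 with an estimated correlation, median 0.26 against cells without a guide with 31 higher and 7 lower). RPS26 (1.15), RPL11 (1.26) and RPS21 (1.05) were higher, RPS2 lower (-1.49). Mitotic genes rose in 8 of 30 (8 adjusted over the list alone, adjusted p = 0.00141, adjusted p = 0.363 with an estimated correlation, median -0.06 against cells without a guide with 4 higher and 8 lower). They included CKS2 (0.96), BUB1 (0.63) and CDK1 (0.56). Heat shock targets rose in 6 of 18 (6 adjusted over the list alone, median 0.39, adjusted p = 0.000366, adjusted p = 0.121 with an estimated correlation). Their median was -0.49 against cells without a guide, with 0 higher and 12 lower. Genes of the unfolded protein response rose in 10 of 23 (11 adjusted over the list alone, adjusted p = 0.00125, adjusted p = 0.251 with an estimated correlation, median 0.08 against cells without a guide with 5 higher and 1 lower). Initiation and elongation factors rose in 13 of 39 and fell in 1 (13 and 2 adjusted over the list alone, adjusted p = 0.00198, adjusted p = 0.116 with an estimated correlation, median 0.05 against cells without a guide with 10 higher and 8 lower). Histone footprints fell in 13 of 37 and rose in 4 (16 and 6 adjusted over the list alone, adjusted p = 0.0354, adjusted p = 0.6 with an estimated correlation, median -0.19 against cells without a guide with 7 higher and 11 lower). EIF4EBP1, an inhibitor of EIF4E, fell by 0.64, and the kinase PIM1 and MYC by 0.74 and 0.62.

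Footprints of 1608 genes changed in sgGIGYF2 (814 higher, 794 lower). The count was 680 without sgGal4 replicate 1 and 844 without sgGIGYF2 replicate 2, and of 33 named values 1 and 4 then lost their call. It was 969 with the joint control. List members past the threshold without sgGal4 replicate 1 were: ribosomal proteins 30 higher and 4 lower (median 0.33), initiation and elongation factors 11 higher (median 0.22), ATF4 targets 11 lower (median -0.35), unfolded protein response 6 higher (median 0.27), heat shock targets 5 higher (median 0.36), mitotic genes 4 higher (median 0.25), histones 1 higher and 7 lower (median -0.16) and proteasome 8 higher (median 0.32).

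The TE of ribosomal proteins was higher in sgGIGYF2 than in sgGal4, but not than in cells without a guide. Of 66 ribosomal protein genes 23 rose in TE and 4 fell (30 and 5 adjusted over the list alone, adjusted p = 8.13e-06, adjusted p = 0.647 with an estimated correlation). Against cells without a guide the list median was -0.02, with 4 higher and 12 lower. RPS24 (1.72, SE 0.27, adjusted p = 0.000382) and RPS25 (1.61, SE 0.23, adjusted p = 0.00011) rose, while RPS2 was lower (-2.67, SE 0.38, adjusted p = 0.00011). Of the initiation and elongation factors 7 of 39 rose, EIF3M (1.42) and EIF4B (1.30) among them, and 1 fell (9 and 2 adjusted over the list alone, adjusted p = 0.0224, adjusted p = 0.495 with an estimated correlation), and against cells without a guide their median was -0.05 (4 higher, 4 lower). Histones rose in 5 of 36 (5 adjusted over the list alone, adjusted p = 0.00791, adjusted p = 0.777 with an estimated correlation, median 0.09 against cells without a guide with 3 higher and 3 lower). Mitotic genes rose in 5 of 30 and fell in 1 (9 and 1 adjusted over the list alone, adjusted p = 0.00157, adjusted p = 0.647 with an estimated correlation, median 0.15 against cells without a guide with 2 higher and 0 lower). Immediate-early and AU-rich mRNAs fell in 3 of 30, SRF (-1.17), JUN (-1.51) and BTG2 (-0.76), and rose in 0 (6 and 0 adjusted over the list alone, adjusted p = 0.0179, adjusted p = 0.647 with an estimated correlation, median -0.20 against cells without a guide with 0 higher and 1 lower). Their total RNA shifted up as a list, with 0 members higher and 1 lower (4 and 1 adjusted over the list alone, adjusted p = 0.0466, adjusted p = 0.611 with an estimated correlation, median 0.13 against cells without a guide with 7 higher and 3 lower). The zinc finger genes ZNF92, ZNF431, ZNF91 and ZNF485, ALG6 and RSRP1 completed the largest increases among genes of at least 10 CPM. RANBP1 (-2.48), ATPAF2, the selenoprotein SEPHS2, TOR2A, UQCRFS1, ZC3H3 and NFATC4 followed RPS2 among the largest decreases there. The TE of RANBP1 (-2.51) and RSRP1 (1.42) changed as much in cells without a guide, so these values are not specific to sgGIGYF2. TE changed for 928 genes, 432 higher and 496 lower. Without sgGal4 replicate 1 the count was 15, without sgGal4 replicate 2 1597, without sgGIGYF2 replicate 1 313 and without sgGIGYF2 replicate 2 80. Of 32 named values 24, 3, 12 and 21 lost their call. The list members that passed without sgGal4 replicate 1 were: ribosomal proteins 4 higher and 1 lower (median 0.35), initiation and elongation factors 1 higher (median 0.19), AU-rich mRNAs 0 (median -0.25), mitotic genes 0 (median 0.23) and histones 0 (median 0.31).

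In footprints, ATF4 targets were lower in sgEIF4E2 than in sgGal4, but not lower than in cells without a guide. In all 10 of 37 fell and 0 rose (14 and 0 adjusted over the list alone, median -0.26, adjusted p = 2.13e-05, adjusted p = 0.0873 with an estimated correlation). The median was 0.69 against cells without a guide, with 25 higher and 1 lower. TRIB3 fell by 0.99 (SE 0.12, adjusted p = 3.24e-07), DDIT3 by 1.08 (SE 0.20, adjusted p = 0.000323) and the serine enzyme SHMT2 by 0.66. In total RNA 8 fell, DDIT3 by 0.96 and ATF5 by 0.93 (9 lower and 1 higher adjusted over the list alone, adjusted p = 0.0499, adjusted p = 0.553 with an estimated correlation), and against cells without a guide the median was 0.50 (22 higher, 0 lower). Footprints of delta globin HBD rose by 1.90 (SE 0.14, adjusted p = 2.2e-13), of the transferrin receptor TFRC by 0.70, and of the platelet integrin ITGA2B by 1.59. Proteasome footprints rose in 9 of 34 and fell in 0 (15 and 0 adjusted over the list alone, adjusted p = 8.29e-06, adjusted p = 0.0375 with an estimated correlation, median 0.03 against cells without a guide with 2 higher and 4 lower). Ribosomal proteins rose in 19 of 67 and fell in 6 (27 and 7 adjusted over the list alone, adjusted p = 0.000105, adjusted p = 0.363 with an estimated correlation, median 0.13 against cells without a guide with 21 higher and 14 lower). Mitotic genes rose in 8 of 30 (9 adjusted over the list alone, adjusted p = 0.000402, adjusted p = 0.334 with an estimated correlation, median 0.06 against cells without a guide with 3 higher and 7 lower). Genes of the unfolded protein response rose in 5 of 23 (7 adjusted over the list alone, adjusted p = 0.00407, adjusted p = 0.295 with an estimated correlation, median 0.05 against cells without a guide with 5 higher and 2 lower). Heat shock targets rose in 3 of 18 (5 adjusted over the list alone, adjusted p = 0.00125, adjusted p = 0.166 with an estimated correlation), but against cells without a guide their median was -0.58 (0 higher, 13 lower). Footprints on mitochondrially encoded mRNAs fell in 6 of 13, MT-ND5 by 0.99 and MT-CO1 by 0.71 (7 adjusted over the list alone, adjusted p = 0.00158, adjusted p = 0.477 with an estimated correlation). Against cells without a guide their median was 0.11 (1 higher, 1 lower).

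In sgEIF4E2 total RNA, histones were lower in 7 of 36 (23 adjusted over the list alone, adjusted p = 1.53e-06, adjusted p = 0.591 with an estimated correlation, median -0.19 against cells without a guide with 1 higher and 4 lower). Ribosomal proteins were lower in 7 of 67 and higher in 4 (26 and 8 adjusted over the list alone, adjusted p = 0.00156, adjusted p = 0.611 with an estimated correlation), but against cells without a guide their median was 0.18 (6 higher, 0 lower). ITGA2B (1.70) and THBS1 (1.51) were higher among 8 megakaryocyte genes (5 higher and 1 lower adjusted over the list alone, adjusted p = 0.00237, adjusted p = 0.301 with an estimated correlation, median 0.63 against cells without a guide with 4 higher and 1 lower). HSPA5 (1.31) and SDF2L1 (0.82) rose in the unfolded protein response (2 of 23, and 5 adjusted over the list alone, adjusted p = 0.0191, adjusted p = 0.505 with an estimated correlation). That list's median was -0.00387 against cells without a guide (2 higher, 2 lower). The mitochondrial protein CHCHD10 (2.56), HSPB1 (2.37), RPS16 (2.33), SEPHS2, LSM10, ITGA2B, HNRNPH3 and PPP1R14A rose most among genes of at least 10 CPM. Alpha-fetoprotein AFP (-2.20, SE 0.23, adjusted p = 7.2e-05), FLT1 (-2.02), the insulin receptor substrate IRS1 (-1.55), ERV3-1 (-1.51), F8, ZNF442 and H2BC21 fell most after EIF4E2 among such genes, which leaves out TIGD1 (-3.97). Of these genes, CHCHD10, HSPB1, HNRNPH3 and PPP1R14A also passed as higher, and AFP, ERV3-1, F8 and H2BC21 as lower, in cells without a guide. CHCHD10 and HSPB1 had 0 counts in sgGal4 replicate 1, so their fold changes depend on that library. The TE of SMIM20 (1.68), RPS25 (1.67), SNHG32, ZNF440, ZNF57, CEP170, RSRP1 and MAGEA3 was highest with the same limit in both assays. That of CHCHD10 (-2.41), RANBP1 (-2.35), SEPHS2, RPS16, RPS2 (-2.11), DMAP1, HSPB1 and EEFSEC was lowest. RSRP1, CHCHD10 and RANBP1 passed the same way in TE in cells without a guide. As lists, ribosomal proteins rose in TE in 17 of 66 and fell in 3 (34 and 5 adjusted over the list alone, adjusted p = 7.95e-07, adjusted p = 0.647 with an estimated correlation), with a median of 0.03 against cells without a guide (2 higher, 5 lower). Histones rose in 4 of 36 (13 adjusted over the list alone, adjusted p = 1.06e-05, adjusted p = 0.694 with an estimated correlation, median 0.16 against cells without a guide with 3 higher and 1 lower). Mitotic genes rose in 2 of 30 (4 higher and 1 lower adjusted over the list alone, adjusted p = 0.00277, adjusted p = 0.647 with an estimated correlation, median 0.03 against cells without a guide with 0 higher and 0 lower). AU-rich mRNAs fell in 1 of 30, JUND at -0.87 (3 adjusted over the list alone, adjusted p = 0.0213, adjusted p = 0.647 with an estimated correlation, median -0.20 against cells without a guide with 0 higher and 0 lower).

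In sgEIF4E2, 498 genes changed in total RNA (296 higher, 202 lower), 752 in footprints (391 and 361) and 346 in TE (138 and 208), and with the replicate block 687 in TE. Left out in turn, sgGal4 replicate 1, sgGal4 replicate 2, sgEIF4E2 replicate 1 and sgEIF4E2 replicate 2 gave 42, 676, 22 and 19 genes in total RNA, 263, 1252, 221 and 207 in footprints, and 1, 1151, 21 and 2 in TE. Of 31, 28 and 25 named values, 19, 8, 22 and 23 (total RNA), 9, 4, 5 and 10 (footprints) and 24, 0, 19 and 23 (TE) lost their call. The joint control gave 30 genes in total RNA, 289 in footprints and 3 in TE. In sgEIF4E2 total RNA the list members past the threshold without sgGal4 replicate 1 were: ribosomal proteins 0 (median -0.21), ATF4 targets 4 lower (median -0.16), unfolded protein response 0 (median 0.10), megakaryocyte genes 1 higher (median 0.81) and histones 0 (median -0.44). In footprints they were: ribosomal proteins 10 higher and 5 lower (median 0.18), ATF4 targets 8 lower (median -0.18), unfolded protein response 1 higher (median 0.20), heat shock targets 2 higher (median 0.23), mitotic genes 3 higher (median 0.20), proteasome 4 higher (median 0.27) and mitochondrially encoded mRNAs 4 lower (median -0.45). In TE they were: ribosomal proteins 1 higher (median 0.42), AU-rich mRNAs 0 (median -0.22), mitotic genes 0 (median 0.20) and histones 0 (median 0.51).

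No gene called after both the GIGYF2 and the EIF4E2 knockdown moved in opposite directions. Of the genes called in total RNA (418 and 498), 113 were higher in both (5.78 for independent lists) and 113 lower (4.56). Of those called in footprints (1608 and 752), 325 were higher and 267 lower in both (33.2 and 29.9). Of those called in TE (928 and 346), 111 were higher in both (6.36), and the shared lower genes also outnumbered those of independent lists (11). Simulated unchanged groups with the same controls shared at most 1 gene per direction, but their lists held under 1 gene on average, so this does not weigh lists of the observed size. Simulations that gave each group the changes of its called genes at other genes, against shared controls, had smaller lists (636 and 286 genes higher in footprints). They shared 5.63 higher and 6.15 lower genes in total RNA (at most 14 and 14), 37.2 and 25.8 in footprints (at most 52 and 36) and 7.4 and 11.3 in TE (at most 13 and 20). The simulated controls vary as the fitted model does, so part of the overlap may still come from the sgGal4 libraries. The overlap is also not particular to these knockdowns: with the total RNA changes of cells without a guide, sgGIGYF2 shared 97 higher and 106 lower genes (21.1 and 23.8 for independent lists) and sgEIF4E2 144 and 119 (32.2 and 21.4). In footprints these were 204 and 207 (95.4 and 88.3) and 107 and 109 (45.8 and 40.2). Tested against each other, the knockdowns differed at 3 genes in total RNA: EIF4E2 (4.31), GIGYF2 (-2.71) and TIGD1 (3.16, SE 0.513, adjusted p = 0.026). In footprints they differed at 28 genes, 14 higher and 14 lower in sgGIGYF2. HBD was lower there by 0.87 (SE 0.131, adjusted p = 0.000157) and the histone H2BC26 by 0.68. THOC3 (-4.16, SE 0.75) had counts near 0 there (0.42 CPM). Mitochondrially encoded MT-CO2 (0.84), MT-CO3 (0.70) and MT-ATP8 (0.89), the receptor KIT (0.58) and CCDC18 (1.03) were higher. In TE edgeR called 0 genes, with 454 at an unadjusted p under 0.05. Limma on the ratio also called 0, DESeq2 called 1 and edgeR with the replicate block 2.

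Across genes, the sgGIGYF2 and sgEIF4E2 log2 changes correlated at r = 0.812 in total RNA, 0.758 in footprints and 0.794 in TE. Genes are not independent replicates, and both comparisons share the sgGal4 libraries: simulated unchanged groups gave 0.63, 0.515 and 0.567. The covariances were 0.159, 0.177 and 0.279 against 0.0621, 0.0488 and 0.0952 in the simulations. With cells without a guide as the control of sgEIF4E2, r was 0.099, 0.238 and 0.494. With only 2 sgGal4 libraries the controls could not be split into groups of 2, so how much of the excess comes from the shared controls is not known. With 1 replicate of each against 1 sgGal4 library that the other did not use, r was 0.436 and 0.339 in total RNA, 0.343 and 0.433 in footprints and 0.377 and 0.382 in TE. With the shared controls, pairs of sgGIGYF2 or sgEIF4E2 with sgZNF598 or sgNEMF gave r of 0.548 to 0.617, 0.462 to 0.594 and 0.716 to 0.761. Their TE covariances were 0.2585 to 0.319, so TE agreement is not particular to sgGIGYF2 with sgEIF4E2. In the direct comparison, leaving out sgGIGYF2 replicate 1, sgGIGYF2 replicate 2, sgEIF4E2 replicate 1 and sgEIF4E2 replicate 2 in turn gave 31, 3, 18 and 3 footprint genes. Of 27 named footprint values 7, 24, 13 and 24 lost their call.

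**Figure D3:**
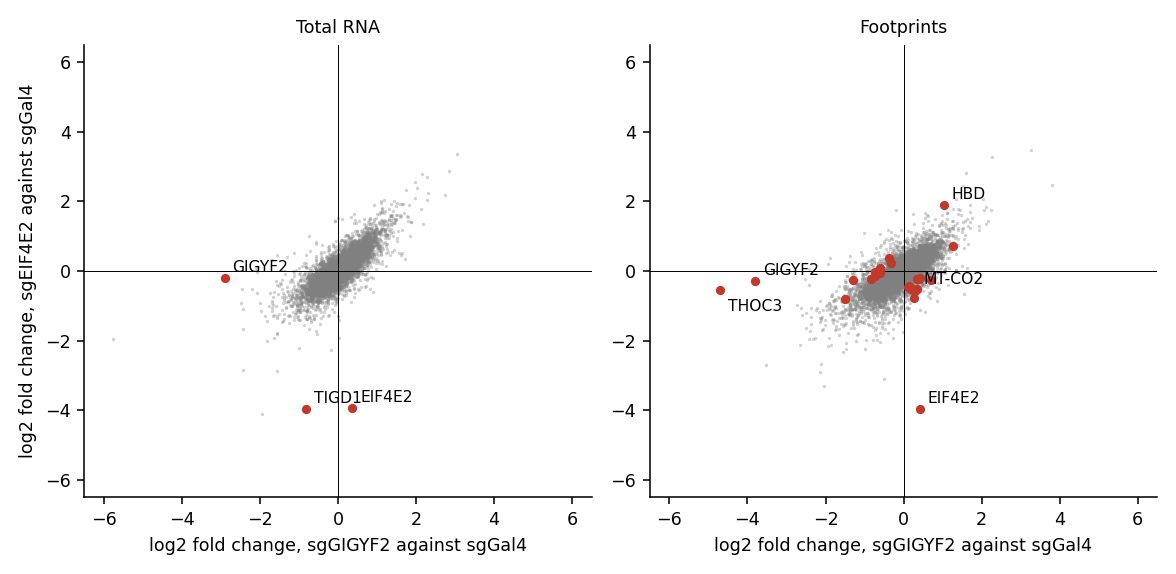
Log2 fold change of each gene against sgGal4 in sgGIGYF2 (horizontal) and sgEIF4E2 (vertical), for total RNA and footprints. Red points are the genes that differ between the knockdowns when tested directly, 3 in total RNA and 28 in footprints, and most genes lie along the diagonal.

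In sgZNF598 the list of monocyte and granulocyte genes was higher and that of proteasome subunits lower in total RNA and footprints. With an estimated correlation only that of monocyte footprints passed. Footprints of lysozyme (LYZ) rose by 1.55 (SE 0.16, adjusted p = 4.07e-09), of AIF1 by 1.12, of the receptor CSF3R by 1.02 and of FCER1G by 0.78. In all, 7 of 10 monocyte and granulocyte genes rose and 0 fell (8 and 1 adjusted over the list alone, median 1.07, adjusted p = 1.11e-05, adjusted p = 0.0375 with an estimated correlation, median 2.61 against cells without a guide with 8 higher and 0 lower). In total RNA 4 of 11 rose, ITGAM by 1.67 and CSF3R by 0.85 (5 adjusted over the list alone, adjusted p = 0.00462, adjusted p = 0.301 with an estimated correlation, median 1.44 against cells without a guide with 8 higher and 0 lower). The red cell anion exchanger SLC4A1 rose by 3.32 in total RNA and 4.16 in footprints, from total RNA levels of 0 and 0.94 CPM in sgGal4. Proteasome mRNAs fell in 12 of 34, PSMB1 by 0.85 and PSMC4 by 0.72, and rose in 1 (14 and 1 adjusted over the list alone, adjusted p = 0.00171, adjusted p = 0.301 with an estimated correlation, median -0.49 against cells without a guide with 0 higher and 19 lower). Their footprints fell in 6 (10 lower and 1 higher adjusted over the list alone, adjusted p = 0.00577, adjusted p = 0.0974 with an estimated correlation, median -0.37 against cells without a guide with 0 higher and 21 lower). Total RNA of mitotic genes fell in 15 of 30, KIF20A by 0.76 and CENPF by 0.75 (18 lower and 1 higher adjusted over the list alone, adjusted p = 1.03e-06, adjusted p = 0.415 with an estimated correlation, median -0.49 against cells without a guide with 0 higher and 21 lower). Histones fell in 19 of 36 (24 lower and 1 higher adjusted over the list alone, adjusted p = 1.02e-06, adjusted p = 0.591 with an estimated correlation, median -0.23 against cells without a guide with 4 higher and 10 lower).

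In sgZNF598 footprints the mitochondrially encoded mRNAs rose in 9 of 13, MT-ATP6 by 1.02 and MT-ND4 by 0.77 (12 adjusted over the list alone, adjusted p = 9.43e-05, adjusted p = 0.363 with an estimated correlation, median 1.09 against cells without a guide with 13 higher and 0 lower). Cholesterol and fatty acid genes fell in 4 of 25, FASN by 0.92 and HMGCS1 by 0.85 (6 adjusted over the list alone, adjusted p = 0.00996, adjusted p = 0.202 with an estimated correlation, median -0.49 against cells without a guide with 1 higher and 14 lower). Ribosomal proteins rose in 22 of 67 and fell in 6 (27 and 9 adjusted over the list alone, adjusted p = 0.00522, adjusted p = 0.52 with an estimated correlation, median 0.14 against cells without a guide with 22 higher and 16 lower). RPL39 rose by 1.33. Of the unfolded protein response, 5 of 23 genes rose, DNAJB9 by 1.06 (7 adjusted over the list alone, adjusted p = 0.00109, adjusted p = 0.251 with an estimated correlation, median 0.04 against cells without a guide with 6 higher and 3 lower). The immediate-early factor EGR1 fell by 1.90 (SE 0.19, adjusted p = 3.14e-09) and the segregase VCP by 0.90, and the interferon-induced PSMB9 and BST2 rose by 2.65 and 0.94. In total RNA CHCHD10 (2.75), RPS16, SEPHS2, SMDT1, RPL28, BRI3, SOCS1 (1.92) and SYCE1 rose most among genes of at least 10 CPM, which leaves out SLC4A1 and SYNGR3 (2.30). CHCHD10, and HSPB1 in TE below, had 0 counts in sgGal4 total RNA replicate 1, so their values depend on that library. FLT1 (-2.97, SE 0.28, adjusted p = 1.9e-05), ZNF598, H2BC21 (-1.88), NDUFAF1, RPL7L1, SLIRP, IFT81 and RPL41 fell most among such genes. Of these, CHCHD10 was also higher and H2BC21 and RPL41 lower in cells without a guide. Under the same limit in both assays, TE was highest for SCOC (2.31), RNF168, UBE2D3, ATP5MK, RPL39 (1.84), ZNF117, RPL41 and FBXO8. It was lowest for CHCHD10 (-3.15), ZNF414, HSPB1, SEPHS2, RBM10, ZC3H3, RPS2 and SOCS1, which leaves out SYNGR3 (-2.76), and CHCHD10 TE was also lower in cells without a guide (-2.11). Histone TE rose in 17 of 36 (23 adjusted over the list alone, adjusted p = 2.82e-06, adjusted p = 0.694 with an estimated correlation, median 0.23 against cells without a guide with 12 higher and 0 lower). Mitotic TE rose in 5 of 30 and fell in 1 (9 and 1 adjusted over the list alone, adjusted p = 0.00972, adjusted p = 0.694 with an estimated correlation, median 0.08 against cells without a guide with 2 higher and 2 lower). AU-rich mRNAs fell in 6 of 30 and rose in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.0179, adjusted p = 0.647 with an estimated correlation, median -0.25 against cells without a guide with 0 higher and 4 lower).

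In sgZNF598, 1493 genes changed in total RNA (828 higher, 665 lower), 1098 in footprints (568 and 530) and 1392 in TE (659 and 733). Without sgGal4 replicate 1, sgZNF598 replicate 1 and sgZNF598 replicate 2 in turn, total RNA gave 353, 340 and 281, footprints 477, 388 and 668, and TE 181, 419 and 364. Of 31, 25 and 28 named values, 9, 9 and 7 (total RNA), 4, 5 and 4 (footprints) and 13, 8 and 7 (TE) lost their call. The joint control gave 748 in TE. In sgZNF598 total RNA the list members past the threshold without sgGal4 replicate 1 were: monocyte genes 2 higher (median 0.55), mitotic genes 4 lower (median -0.39), histones 8 lower (median -0.52) and proteasome 5 lower (median -0.34). In footprints they were: ribosomal proteins 19 higher and 6 lower (median 0.23), unfolded protein response 2 higher (median 0.19), monocyte genes 6 higher (median 0.99), cholesterol genes 7 lower (median -0.29), proteasome 2 lower (median -0.19) and mitochondrially encoded mRNAs 7 higher (median 0.56). In TE they were: AU-rich mRNAs 1 lower (median -0.24), mitotic genes 0 (median 0.21) and histones 7 higher (median 0.67).

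In sgNEMF the mitotic list was lower in total RNA and the histone list higher in footprints, but neither passed with an estimated correlation. CDC20, an activator of the anaphase-promoting complex, fell by 0.71 in total RNA (SE 0.13, adjusted p = 0.0118), HMMR by 0.79 and CENPF by 0.70. In all, 9 of 30 mitotic genes fell (18 adjusted over the list alone, adjusted p = 2.16e-08, adjusted p = 0.415 with an estimated correlation, median -0.54 against cells without a guide with 0 higher and 21 lower). Histone total RNA fell in 8 of 36 (22 adjusted over the list alone, adjusted p = 1.91e-06, adjusted p = 0.591 with an estimated correlation, median -0.21 against cells without a guide with 3 higher and 7 lower). Histone footprints, in turn, rose in 12 of 37, H2BC7 by 1.65 and H2BC5 by 1.08 (15 higher and 1 lower adjusted over the list alone, adjusted p = 9.43e-05, adjusted p = 0.366 with an estimated correlation, median 0.36 against cells without a guide with 22 higher and 6 lower). Histone TE rose in 16 of 36 (23 adjusted over the list alone, adjusted p = 1.82e-10, adjusted p = 0.647 with an estimated correlation, median 0.42 against cells without a guide with 11 higher and 0 lower). ATF5 rose by 0.80 in total RNA and 1.31 in footprints and the stress cytokine GDF15 by 0.67 in footprints, whereas MTHFD2 fell by 0.63 in total RNA. The ATF4 list shifted up in total RNA with 1 higher and 1 lower (1 and 1 adjusted over the list alone, adjusted p = 0.0499, adjusted p = 0.553 with an estimated correlation, median 0.72 against cells without a guide with 28 higher and 0 lower). Mitochondrially encoded mRNAs rose in footprints in 9 of 13, MT-ND6 by 0.99 (11 adjusted over the list alone, adjusted p = 2.7e-05, adjusted p = 0.363 with an estimated correlation, median 1.12 against cells without a guide with 12 higher and 0 lower). Ribosomal proteins rose in 26 of 67 and fell in 5 (32 and 6 adjusted over the list alone, adjusted p = 9.8e-05, adjusted p = 0.363 with an estimated correlation, median 0.21 against cells without a guide with 27 higher and 15 lower). Monocyte genes rose in 2 of 10, LYZ by 0.98 and FCER1G by 0.80 (5 adjusted over the list alone, adjusted p = 0.0038, adjusted p = 0.116 with an estimated correlation, median 1.64 against cells without a guide with 7 higher and 0 lower). Of the unfolded protein response, 2 of 23 rose (2 adjusted over the list alone, adjusted p = 0.0179, adjusted p = 0.342 with an estimated correlation, median 0.05 against cells without a guide with 5 higher and 6 lower).

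Among genes of at least 10 CPM, the largest total RNA increases in sgNEMF were RPS16 (2.37), SEPHS2 (2.33), SMDT1, the RNA-binding protein PCBP1 (1.89), SYCE1, RPL28, HMGN5 and ZFAND3. The largest decreases after NEMF were FLT1 (-1.54), H2BC21 (-1.53), RPL41, MICU3, CD52, H2AC17 and GEMIN6. PCBP1 was also higher, and H2BC21, RPL41, MICU3, CD52 and H2AC17 lower, in cells without a guide. With that limit in both assays, TE was highest for H2BC7 (2.18), RPL39 (2.17), MSANTD4, RPL41, EMP3, RPS24, RBBP9 and H2BC5. It was lowest for SEPHS2 (-2.69), ATPAF2, SMDT1, HSPB1, CEP131, RPS16, ZC3H3 and PRKCD, of which HSPB1 had 0 counts in sgGal4 total RNA replicate 1. Ribosomal protein TE rose in 16 of 66 and fell in 6 (22 and 10 adjusted over the list alone, adjusted p = 0.00339, adjusted p = 0.647 with an estimated correlation), but against cells without a guide their median was -0.15 (8 higher, 16 lower). Mitotic TE rose in 2 of 30 and fell in 1 (2 and 1 adjusted over the list alone, adjusted p = 0.00449, adjusted p = 0.694 with an estimated correlation, median 0.09 against cells without a guide with 2 higher and 1 lower). In sgNEMF, 451 genes changed in total RNA (306 higher, 145 lower), 641 in footprints (338 and 303) and 704 in TE (281 and 423). Left out in turn, sgGal4 replicate 1, sgGal4 replicate 2, sgNEMF replicate 1 and sgNEMF replicate 2 gave 3, 624, 223 and 1 genes in total RNA, 187, 1268, 377 and 132 in footprints, and 92, 1293, 605 and 40 in TE. Of 24, 17 and 24 named values 23, 8, 6 and 23 (total RNA), 3, 0, 1 and 5 (footprints) and 9, 1, 1 and 13 (TE) lost their call. The joint control gave 180 genes in total RNA and 196 in TE. In sgNEMF total RNA the list members past the threshold without sgGal4 replicate 1 were: ATF4 targets 0 (median 0.10), mitotic genes 0 (median -0.31) and histones 0 (median -0.40). In footprints they were: ribosomal proteins 19 higher and 3 lower (median 0.22), unfolded protein response 0 (median 0.12), monocyte genes 2 higher (median 0.52), histones 13 higher (median 0.27) and mitochondrially encoded mRNAs 4 higher (median 0.54). In TE they were: ribosomal proteins 7 higher and 2 lower (median 0.25), mitotic genes 0 (median 0.15) and histones 8 higher (median 0.74).

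**Figure D4:**
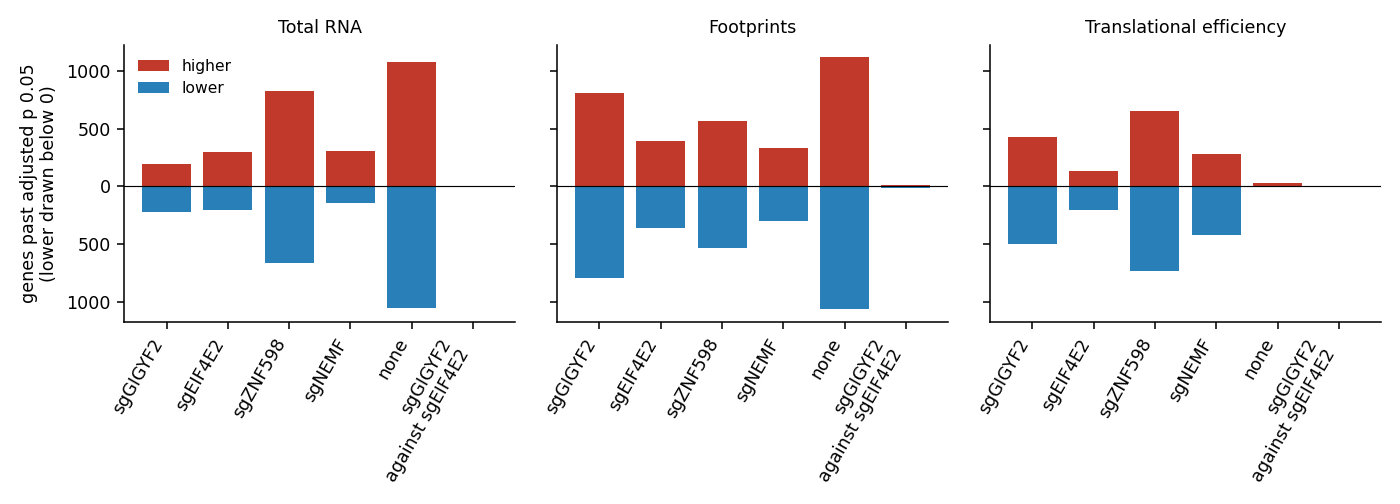
Number of genes past an adjusted p of 0.05 in each comparison, by readout, with higher genes above 0 and lower genes below (edgeR, 2 libraries per group). The direct comparison of sgGIGYF2 with sgEIF4E2 has 3, 28 and 0 genes, against 346 to 1608 for the knockdowns against sgGal4.

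Some genes moved the same way in all 4 knockdowns: 26 were higher and 10 lower in total RNA, 77 and 55 in footprints, and 60 and 110 in TE. HSPA5, the deubiquitinase USP21 and RPL8 were among those higher in total RNA in all 4, and FLT1, H2BC21, MTHFD2 and HMMR among those lower. In TE, the ribosomal proteins RPL39, RPL41, RPS24, RPS25 and the histones H2BC7 and H2BC8 were higher in all 4, and RPS2, FASN, GATA1, SEPHS2 and HSPB1 lower. All 4 comparisons use the same sgGal4 libraries, and how much of this sharing comes from them is not known. In total RNA, 298 of the 418 genes called in sgGIGYF2, 336 of 498 in sgEIF4E2, 1382 of 1493 in sgZNF598 and 407 of 451 in sgNEMF moved in the same direction against cells without a guide, and 114, 103, 970 and 237 passed there. In footprints 1395 of 1608, 642 of 752, 1069 of 1098 and 623 of 641 did, and 908, 398, 932 and 540 passed. In TE 907 of 928, 335 of 346, 1373 of 1392 and 697 of 704 did, and 449, 78, 814 and 345 passed. The calls used the same knockdown libraries, so some agreement is built in.

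Footprints of cells without a guide were lower for ATF4 targets and erythroid genes and higher for heat shock targets than those of sgGal4 cells, also with an estimated correlation. TRIB3 was lower by 1.84 in total RNA (SE 0.12, adjusted p = 1.86e-08) and by 1.99 in footprints. Of 37 ATF4 targets 27 were lower in total RNA and 31 in footprints, with 1 higher in each (28 and 31 lower and 1 higher adjusted over the list alone, medians -0.72 and -0.85, adjusted p = 3.24e-11 and 5.21e-18, adjusted p = 0.273 and 0.0292 with an estimated correlation). Heat shock targets were higher in 11 of 19 in total RNA and 15 of 18 in footprints, DNAJA1 by 1.28 and HSPA4 by 0.92 in total RNA (12 and 15 adjusted over the list alone, adjusted p = 7.92e-06 and 3.94e-09, adjusted p = 0.273 and 0.0375 with an estimated correlation). Erythroid genes were lower, HBD by 1.77 in total RNA, in 11 of 28 with 1 higher (16 and 3 adjusted over the list alone, adjusted p = 0.00105, adjusted p = 0.301 with an estimated correlation). In footprints 12 of 27 were lower and 4 higher (15 and 4 adjusted over the list alone, adjusted p = 0.000131, adjusted p = 0.0375 with an estimated correlation). Monocyte genes were lower in 7 of 11 in total RNA, CSF3R by 2.28 (8 adjusted over the list alone, adjusted p = 0.000284, adjusted p = 0.273 with an estimated correlation). In footprints 5 of 10 were lower (5 adjusted over the list alone, adjusted p = 0.000973, adjusted p = 0.0873 with an estimated correlation). Ribosomal protein mRNAs were lower in 30 of 67 (40 adjusted over the list alone, adjusted p = 4.41e-07, adjusted p = 0.543 with an estimated correlation). Their TE was higher in 8 of 66, RPS18 by 1.57 (32 higher and 1 lower adjusted over the list alone, adjusted p = 3.02e-16, adjusted p = 0.377 with an estimated correlation). Among genes of at least 10 CPM, the integrin ITGA4 (2.43), RANBP1 (2.07), NDUFAF8 and CRYBG1 were most raised in total RNA. The sodium channel SCN4A (-5.31), BATF2 (-4.97), SH2B2 and SEL1L3 were most lowered. With that limit in both assays, TE was most raised for RPS18, RSRP1, GAPDH (1.35) and RPS6, and most lowered for RANBP1 (-2.51), PPP2R1B, UCP2 and PIGW.

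In footprints of cells without a guide, proteasome subunits were higher in 13 of 34 (14 adjusted over the list alone, adjusted p = 0.000241, adjusted p = 0.0375 with an estimated correlation). Mitotic genes were higher in 14 of 30 and lower in 2 (15 and 2 adjusted over the list alone, adjusted p = 0.000482, adjusted p = 0.334 with an estimated correlation). Initiation and elongation factors were higher in 16 of 39 and lower in 5 (18 and 6 adjusted over the list alone, adjusted p = 0.0126, adjusted p = 0.187 with an estimated correlation). Cholesterol genes were higher in 11 of 25 and lower in 2 (12 and 2 adjusted over the list alone, adjusted p = 0.00732, adjusted p = 0.187 with an estimated correlation). Mitochondrially encoded mRNAs were lower in 10 of 13 (11 adjusted over the list alone, adjusted p = 0.0095, adjusted p = 0.546 with an estimated correlation). Megakaryocyte genes were lower in 5 of 9 (5 adjusted over the list alone, adjusted p = 0.0548, and 0.0495 with the replicate block). Proteasome total RNA was higher in 8 of 34 (9 adjusted over the list alone, adjusted p = 0.0473, adjusted p = 0.415 with an estimated correlation). In TE, factors of initiation and elongation were higher in 4 of 39 (7 higher and 2 lower adjusted over the list alone, adjusted p = 0.00433, adjusted p = 0.377 with an estimated correlation). Mitotic genes and histones shifted up with 0 members past the threshold (0 and 1 adjusted over the list alone, adjusted p = 0.00257 and 0.00791, adjusted p = 0.647 and 0.777 with an estimated correlation). The cells without a guide also lacked the virus, the reporter and the sort, so the source of these differences cannot be assigned. In total RNA 2132 genes differed (1079 higher, 1053 lower), in footprints 2189 (1123 and 1066) and in TE 42 (34 and 8), or 72 with the replicate block. Left out in turn, sgGal4 replicate 1, sgGal4 replicate 2 and the cells' replicates 1 and 2 gave 1476, 1353, 2670 and 992 genes in total RNA, 1817, 1872, 1262 and 1220 in footprints and 17, 128, 129 and 7 in TE. Of 32, 36 and 14 named values 0, 4, 0 and 1, then 0, 0, 0 and 1, then 8, 5, 1 and 10 lost their call.

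**Figure D5:**
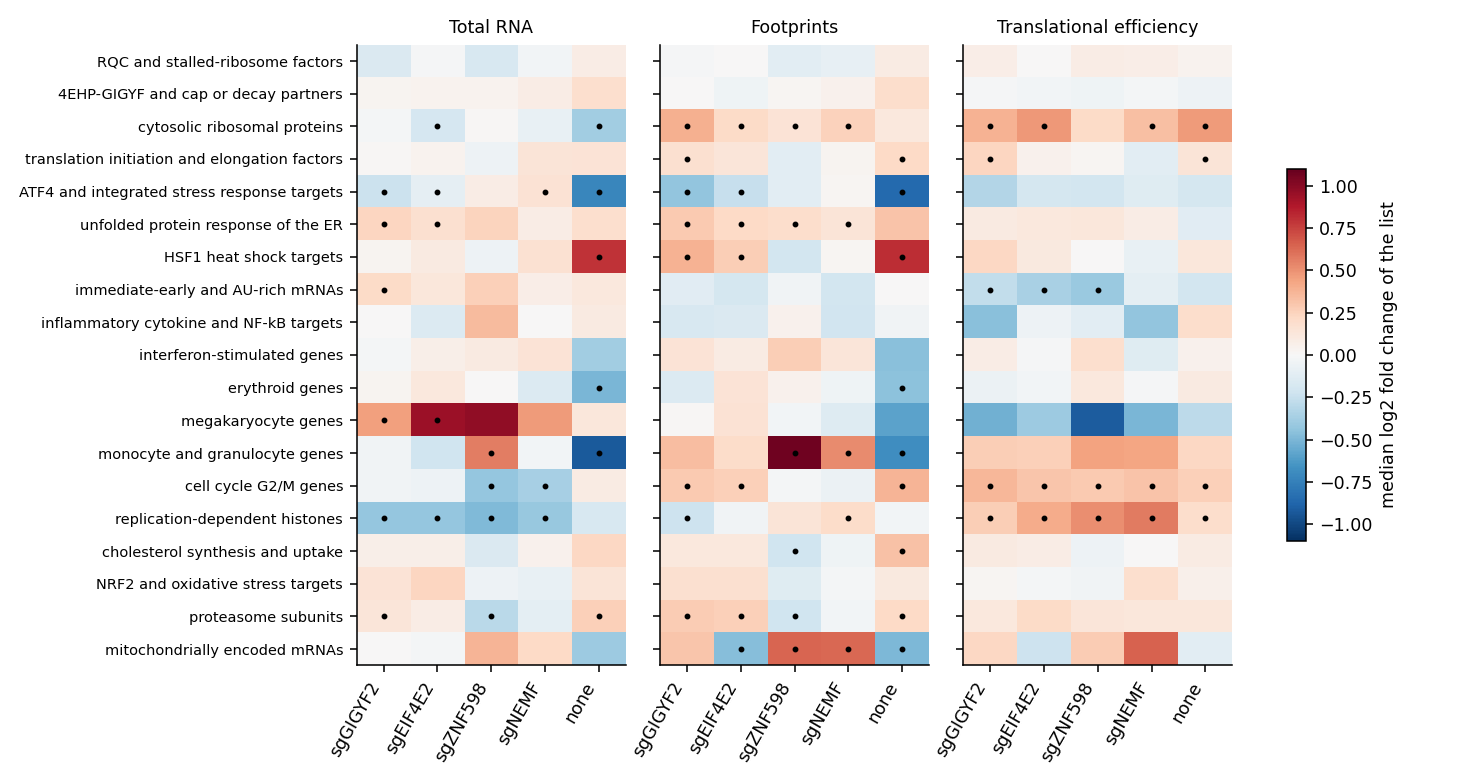
Median log2 fold change against sgGal4 of the 19 gene lists in 5 comparisons, for total RNA, footprints and TE (colour scale on the right). A dot marks a camera adjusted p under 0.05 with the preset correlation, of which only 8 footprint tests passed with an estimated correlation.

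The remaining lists did not pass in any comparison. Of 34 factors of ribosome-associated quality control, 3 passed in sgGIGYF2 total RNA, USP21 (0.92) and EIF5A (0.59) higher and SKIC3 (-0.47) lower (3 adjusted over the list alone, median -0.16, adjusted p = 0.374). In sgZNF598 6 passed, the silenced ZNF598 among them (6 adjusted over the list alone, adjusted p = 0.0517). ABCE1 (-0.57) and PELO (-0.75), which split stalled ribosomes, were lower. Of all genes tested there 15% changed, so these calls do not set the list apart. Partners of 4EHP and GIGYF and decay factors passed in 2 of 38 in sgGIGYF2 total RNA, GIGYF2 and the deadenylase PAN2 (-0.59), and in 3 in sgEIF4E2 with EIF4EBP1 (-0.41) (2 and 3 adjusted over the list alone, adjusted p = 0.726 and 0.702). Of 9 inflammatory cytokine genes CSF1 rose in sgGIGYF2 (1.48) and sgEIF4E2 (1.45) total RNA (1 and 1 adjusted over the list alone, adjusted p = 0.937 and 0.421). Interferon-stimulated genes passed in 2 of 16 in sgZNF598 total RNA (2 adjusted over the list alone, adjusted p = 0.407). NRF2 targets passed in 3 of 15 in sgGIGYF2 total RNA, TXN (0.71), ME1 (0.90) and ABCC1 (0.64) (3 adjusted over the list alone, adjusted p = 0.214). In sgZNF598 PRDX1 (-0.97) and NQO1 (-0.87) fell and ABCC1 (0.93) rose (2 higher and 4 lower of 15, and the same adjusted over the list alone, adjusted p = 0.453).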

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

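The tests of TE against cells without a guide, of ATF4 targets in the other knockdowns, of the dCas9 transcript and of reporter TE were chosen after the results they weigh were seen; the others were chosen before.

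Footprints in 3′ UTRs were not used in the comparisons and were above the sgGal4 level in 3 knockdowns. They made up 0.42% of footprints in sgGIGYF2 (libraries 0.418 and 0.421), 0.47% in sgZNF598 (0.456 and 0.484) and 0.436% in sgNEMF (0.410 and 0.462), against 0.345% in sgGal4 (0.305 and 0.385; n = 2 each). The sgEIF4E2 mean was 0.386% (0.380 and 0.393), so its lower library lay within the sgGal4 range. Without the 10 genes with the most 3′ UTR footprints the means were 0.395%, 0.441% and 0.411%, against 0.322% in sgGal4. These shares were not compared by a test, and no explanation was tested.

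Tested directly, sgGIGYF2 and sgEIF4E2 differed at 3 genes in total RNA (the 2 targets and TIGD1) and 28 in footprints. Most footprint calls were lost without replicate 2 of either.

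TE changed in the same direction in all 4 knockdowns at 170 genes, by a direction-signed median of 1.09 averaged over the knockdowns (SD 0.0923 across them), made up of 0.503 in footprints and -0.546 in total RNA. Against cells without a guide the same genes still moved by 0.751, without sgGal4 replicate 1 by 0.833 and without sgGal4 replicate 2 by 1.45. These genes were picked by calls that used the same knockdown and sgGal4 libraries, so some shift the same way is built in. No value expected from that selection was computed, so these checks cannot weigh the sgGal4 libraries, or replicate 1 alone, as the cause. The calls that define the set also depend on that replicate: without it sgEIF4E2 lost nearly all its TE calls. The genes with higher TE were short (median coding length 299 against 1044 for all genes and 1320 for those with lower TE). TE change fell with length in the knockdowns (rho -0.0973 to -0.239) but not in cells without a guide (0.0662). Removing this trend left a shift of 1.0, which cannot weigh length in genes picked by their calls. A technical difference of the 8 knockdown libraries of each assay from the 4 others stays open, and GC content was not tested without sequence. A shared response to the knockdowns remains a hypothesis beside these.

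ATF4 targets were lower in sgGIGYF2 and sgEIF4E2 footprints, with a mean list median of -0.345, and with an estimated correlation only the sgGIGYF2 list passed. A raised stress response in the sgGal4 cells, with no change in any knockdown, would have lowered them in every knockdown. The medians of sgZNF598 and sgNEMF were -0.1135 and 0.017 (mean -0.0482). A raised level in sgGal4 together with a rise in sgZNF598 and sgNEMF would give the same values, so this test cannot decide. Without sgGal4 replicate 1 the mean for sgGIGYF2 and sgEIF4E2 was -0.262, which leaves open how much of the shift comes from that library. Against cells without a guide the list medians were positive in all 4 knockdowns (0.44 in sgGIGYF2, 0.69 in sgEIF4E2, 0.72 in sgZNF598 and 0.97 in sgNEMF), so the 2 controls disagree on the direction. A lower stress response after loss of GIGYF2 or 4EHP therefore rests on the sgGal4 control, and the difference between knockdowns was not tested for the list.

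Reporter footprints were higher in sgGIGYF2. Without sgGal4 replicate 1 the change was 0.746, which argues against that library as the source, and dCas9 footprints moved the other way (-0.544, adjusted p = 0.0113), which argues against a rise of all engineered transcripts. Reporter TE was at 0.398, just over 2 SE (0.189) above 0, but with an adjusted p of 0.17, and it passed in 0 of 11 alternatives. A bound of 2 SE alone, the criterion first set, would have argued against a rise of reporter RNA as the whole cause. With the adjusted p required as well, a condition added after the value was seen, more reporter RNA and more ribosomes per reporter RNA cannot be told apart. Differences between the sorted populations in reporter integration were not tested.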

How the results depend on the processing

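Only exon reads and the effect correlations without sgGal4 replicate 1 were added after the data were seen. Of 5133 alternative values of 456 named values, 4237 kept direction and side of the threshold, 873 kept direction and no longer passed, 7 passed where they had not, and 16 reversed. For libraries left out, the lone sample is assumed to vary like the other groups. The cause was not tested for any value below.

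Without a filter on low counts, total RNA gave 1032 genes in sgGIGYF2, 1140 in sgEIF4E2, 1107 in sgNEMF and 14 in the direct comparison of sgGIGYF2 with sgEIF4E2; that comparison gave 47 in footprints and 3 in TE, and TE gave 552 in sgEIF4E2 and 73 in cells without a guide. With exon reads, total RNA gave 1255 (sgGIGYF2), 1082 (sgEIF4E2), 2648 (sgZNF598), 928 (sgNEMF), 4384 (cells without a guide) and 5 (direct). A fit of only the 2 groups gave in total RNA 682 for cells without a guide and 7 for the direct comparison, in footprints 954 (sgGIGYF2), 623 (sgZNF598), 251 (sgNEMF) and 48 (direct), and in TE 512 (sgGIGYF2), 375 (sgNEMF) and 3 (cells without a guide). DESeq2 gave 458 in sgEIF4E2 footprints, 9 in direct footprints and 88 in TE of cells without a guide, and limma on the ratio gave 25 there.

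With sgGal4 and cells without a guide as a joint control, total RNA gave 15 (sgGIGYF2), 30 (sgEIF4E2) and 180 (sgNEMF), footprints 969 (sgGIGYF2) and 289 (sgEIF4E2), and TE 299, 3, 748 and 196 (sgGIGYF2, sgEIF4E2, sgZNF598, sgNEMF). Values that reversed there were RANBP1 (-0.15) in sgGIGYF2 total RNA, TRIB3 (0.040) in sgEIF4E2 total RNA, DNAJA1 (-0.091), HSPD1 (-0.021) and HSP90AB1 (-0.066) in sgGIGYF2 footprints and AHSA1 (-0.00731) in sgEIF4E2 footprints. These 2 control groups differed at 2132 genes in total RNA.

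Deviations of total RNA libraries of the same number correlated by more than 0.1 in 8 of 15 pairs of groups (-0.303 to 0.483, median 0.119), and the labels give them no shared pool, so the numbers were not taken as pairs. A replicate block there gave 854 genes in sgGIGYF2, 894 in sgEIF4E2 and 827 in sgNEMF, with ATF4 targets in sgEIF4E2 at an adjusted p of 0.0755 and mitochondrially encoded mRNAs in cells without a guide at 0.0202. In TE the block gave 687 in sgEIF4E2, 72 in cells without a guide and 2 in the direct comparison. For footprints and TE it changed no other call of a list than that of megakaryocyte genes in footprints of cells without a guide (0.0495).

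With each library left out in turn, total RNA counts ranged from 13 to 678 in sgGIGYF2, 19 to 676 in sgEIF4E2, 281 to 1278 in sgZNF598, 1 to 624 in sgNEMF, 992 to 2670 in cells without a guide and 2 to 2 in the direct comparison. Footprint counts ranged from 680 to 2001, 207 to 1252, 388 to 1520, 132 to 1268, 1220 to 1872 and 3 to 31 in the same order. TE counts ranged from 15 to 1597, 1 to 1151, 181 to 1792, 40 to 1293, 7 to 129 and 0 to 0. Without sgGal4 replicate 1, all genes called in total RNA in the 4 knockdowns kept their direction, but most were not called again.

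The sgGIGYF2 and sgEIF4E2 effect correlation was 0.099 in total RNA, 0.238 in footprints and 0.494 in TE with cells without a guide as control of sgEIF4E2, and 0.436 and 0.339, 0.343 and 0.433, and 0.377 and 0.382 with no shared library. In TE it was 0.847 for genes of at least 10 CPM, and without sgGal4 replicate 1 it was 0.80, 0.766 and 0.764 in the 3 readouts. With cells without a guide as the other control the total RNA correlations of sgGIGYF2 with sgZNF598 (-0.028) and sgNEMF (-0.090), and of sgEIF4E2 with sgZNF598 (-0.026) and sgNEMF (-0.069), reversed. The reporter reversed in sgEIF4E2 footprints (-0.019 without sgGal4 replicate 2, -0.028 without sgEIF4E2 replicate 1), in sgZNF598 without sgZNF598 replicate 2 (0.017 in footprints, 0.039 in TE), and in sgNEMF TE (-0.00311 with DESeq2 size factors, -0.011 without a filter, -0.0029 with DESeq2, -0.015 with only 2 groups, -0.035 without sgGal4 replicate 2, -0.083 without sgNEMF replicate 2). None of these had passed the test. With each library left out it ranged from -0.028 to 0.26 in sgEIF4E2 footprints, -0.47 to 0.017 in sgZNF598 footprints, -0.337 to 0.039 in sgZNF598 TE and -0.083 to 0.084 in sgNEMF TE.

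With an estimated correlation, 0 of 24 list calls in total RNA, 8 of 35 in footprints and 0 of 19 in TE were kept.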

Other observations

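Of the genes called after both ZNF598 and NEMF knockdown, 0 moved in opposite directions. Of these genes, 233 were higher and 91 lower in total RNA (25.5 and 9.71 for independent lists), 202 and 187 in footprints (20 and 16.8) and 201 and 339 in TE (19.8 and 33.1). The total RNA overlap was nearly all lost without sgGal4 replicate 1 or sgNEMF replicate 2. Simulated groups with independent changes and the same controls, whose lists were smaller (689 and 264 genes higher in total RNA), shared at most 34 and 29 genes in total RNA, 32 and 36 in footprints and 38 and 45 in TE. Part of the overlap may still come from the shared sgGal4 libraries. The log2 changes correlated at 0.742, 0.644 and 0.749 in turn, where unchanged groups with the same controls gave 0.637, 0.434 and 0.519.

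In footprints, 36 called genes were higher in both sgZNF598 and cells without a guide and 33 lower in both, while 139 genes higher in sgZNF598 were lower in cells without a guide and 198 lower in sgZNF598 were higher there. Simulated groups with independent changes and the same sgGal4 controls shared 68.0 higher and 51.3 lower genes on average (66.6 and 59.0 for independent lists of the observed size), with 44.8 and 59.4 in opposite directions. In total RNA, 136 were higher and 71 lower in both (71.6 and 64.9 simulated) and 97 and 69 were opposite (57.6 and 54.4).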
